A study of Mus musculus with 2 samples.

How the data were processed

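RNA from sorted splenic regulatory T cells of 1 wild-type and 1 Bach2 knockout sample was labelled with biotin and hybridised to Illumina mouse expression BeadChips, a platform on which oligonucleotide probes on beads report 1 intensity per probe and sample. Cells were sorted by flow cytometry, and total RNA was extracted with a commercial kit and labelled by the array maker's standard procedure, per the labels' protocols. The number of animals behind each sample is not given in the sources used here. The scanning software, its version and the background method are not given in the sources used here.

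The authors deposited a table of intensity values, 1 per probe and array, that its header calls non-normalized, with a detection p-value for each. The deposited intensity values were background-subtracted, since 30.4% of them on the wild-type array and 29.5% on the knockout array were below 0. The authors also deposited a series matrix. Its intensity values were, for each array, a straight-line function of the first table (slope 0.782 and intercept 86.6 for wild type, slope 0.779 and intercept 83.3 for the knockout, residuals of at most 0.0091). They are thus on a linear scale with a constant left in and no centring of genes, and the column medians were 99.7 and 95.6. Both tables hold the same measurements, so the second is not independent.

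Probes were named through GEO's platform annotation. Of 25697 probes, 23978 had 1 gene symbol, none had several and 1719 were not listed there and are unnamed here. For 23962 of the named probes the gene number matched RefSeq's gene table, with the same symbol. No listed probe was paired with Bach2. Gene positions are not given, since no genome was used.

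From the deposited intensities, background was corrected by normexp convolution with the noise estimated from the detection p-values, an offset of 16 was added, the arrays were quantile normalized and log2 was taken (neqc in limma 3.58.1, R 4.3.3). A probe was called detected at a detection p-value under 0.01. A gene was represented by its brightest detected probe by the mean of both arrays. Genes detected on at least 1 array were compared. For a gene not detected on 1 array, only a lower bound of the fold was counted, the brighter value against the higher of the gene's own value and the dimmest detected probe on the other array (log2 5.80 for wild type and 5.81 for the knockout). For 5 genes the brightest probe was undetected on 1 array while another probe was detected there; they were counted by the same bound and not ranked by size, and none reached 2-fold. The offset pulls differences of dim genes towards 0. Quantile normalization assumes that the 2 arrays share 1 distribution, so a general shift of all genes cannot be seen.

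With 1 array per genotype no test has residual degrees of freedom, so no p-value or SE is given for any difference. Genes were counted at a fold threshold of 2. Before the data were examined, 30 gene lists were fixed: 18 of T cell states and pathways, 7 of markers of other cell types, and 5 of lineage, reference, ribosomal, stress and sex-linked genes. For each list with at least 5 detected members, the median difference was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins. Members undetected on 1 array entered this median at their normalized value, and only the counts used their bound. A list outside percentiles 2.5 to 97.5 was said to stand apart, as a description of these 2 arrays. Members were counted at 1.5-fold. The genes named followed a rule made at the same time: Bach2, the 15 largest differences in each direction among genes detected on both arrays, the 5 largest bounds in each direction among genes detected on 1 array, and members of the fixed lists, with a list's largest differences, transcription factors and cytokines preferred. Genes of the further families were chosen after their values were seen.

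The steps were tested on simulated data, a pair of arrays made from the real intensities, with 50 probes changed for each fold and direction, in a run with 8788 genes. Of probes simulated 3-fold higher, 98.0% were called at least 2-fold higher (median estimate 1.48 on the log2 scale), and of probes simulated 3-fold lower 92.0% (median -1.41). Of probes simulated exactly 2-fold higher 36.0% were called and of those 2-fold lower 34.0%, and of unchanged probes 0.056%. Of 1000 random lists of 20 genes, 6.8% fell outside the percentile limits, and all lists shifted by 0.5 were called higher. Noise was drawn independently for each probe, with its spread set from the differences between the 2 real arrays at bright probes. The simulation holds no animal effect that moves genes together. Changed probes were drawn from those detected on both arrays, so the call rates do not cover genes counted by their bound.

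Alternatives covered the background correction, the normalization (median scaling, cyclic loess), the offset (1 and 50), the series matrix values, the detection filter, the choice among probes, the fold threshold and the make-up and matching of lists. An alternative that left out genes of the other cell type lists and the sex list was added after the data were seen. Without background correction, values under 1 after the offset were set to 1 before log2. The number of arrays, 1 per genotype, limits the precision of every value, and genotype cannot be told apart from array, animal, donor age or the day of sorting. Figures were drawn with matplotlib 3.10.9 and list tests run in Python 3.11.15.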

Results

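Gene expression was profiled in regulatory T cells, a CD4 T cell subset that restrains immune responses, sorted from mouse spleen by surface CD4, CD25 and GITR. The cells came from C57BL/6 wild-type mice or from mice lacking Bach2, a bZIP transcription factor that acts mainly as a repressor in lymphocytes. The comparison asks which transcripts differ in these cells when Bach2 is absent. There was 1 array per genotype, and the labels gave a donor age of 6 weeks for wild type and 7 weeks for the knockout, both male. Because there was 1 array per group, no difference has a replicate error or a p-value, and each describes these 2 samples. The only available measure of technical scatter was the SD of the log2 difference between probes of the same gene. This SD was 0.22, over 1734 genes with several probes detected on both arrays. It does not cover error that all probes of a gene share. Of 25697 probes, 10431 were detected on the wild-type array and 10373 on the knockout array. These gave 7611 named genes, of which 6994 were detected on both arrays, 328 on the wild-type array only and 284 on the knockout array only. The log2 intensities of the detected probes correlated across probes with a Pearson r of 0.969, and probes are not independent replicates. Every log2 difference is knockout minus wild type.

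No probe of the annotation used here was paired with Bach2, so the deleted gene was not analysed here and the array gave no check of the knockout label. Transcripts that define the sorted population were at like levels on the 2 arrays. Foxp3, the lineage-defining factor of regulatory T cells, differed by -0.10 at its brightest probe, and its other probes differed by -0.37 and 0.11. Il2ra, which encodes CD25, differed by -0.02, Ctla4 by -0.09, Ikzf2 (Helios) by 0.13 and Tnfrsf18, which encodes GITR, by 0.19. The 14 detected T lineage genes had a median difference of -0.05 and none reached 1.5-fold, with Cd4 at -0.01 and Cd3e at -0.05.

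The knockout array had more genes above the 2-fold line than below it. In all, 249 genes (3.27% of those compared) were at least 2-fold higher in the knockout and 118 (1.55%) were at least 2-fold lower. Of these, 220 and 99 were detected on both arrays, and 29 and 19 were detected on 1 array only and were counted by the lower bound of their fold. The genes that were highest in the knockout relative to wild type, among those detected on both arrays, included cytokine and chemokine genes: Ccl4, an inflammatory chemokine, was 5.57-fold higher, Il4 was 4.57-fold higher and Ifng was 4.44-fold higher. The largest difference upwards was that of Lilrb4a, an inhibitory immunoglobulin-like receptor, which was 7.67-fold higher at its 1 detected probe, followed by 6430571L13Rik at 6.75-fold. Plac8 was 5.28-fold higher, Gata2, a transcription factor of mast cells, basophils and progenitors, 4.75-fold, and Scin, an actin-severing protein, 4.28-fold. Gata2 was barely above the dimmest detected probe on the wild-type array (log2 5.83 against 5.80). Slc15a3 was 4.17-fold higher, Il17rb, a subunit of the interleukin 25 receptor, 4.15-fold, Depdc1b 3.96-fold, Cenph 3.90-fold, Cxcr6 3.90-fold, Ccn4 3.83-fold and Rrm2, a ribonucleotide reductase subunit, 3.76-fold. At the other end, Gucy1a1, a soluble guanylate cyclase subunit, was 13.6-fold lower, and its other probes differed by -2.39 and -2.16. Igfbp4, which is high in naive T cells, was 9.51-fold lower, with a second probe at -3.59. Atp1b1 was 6.23-fold lower, Ager 5.62-fold, Scg5 5.19-fold, Amigo2 4.60-fold, Zfp608 4.53-fold, Ly6c1 4.23-fold, Tdrp 4.10-fold and Pik3ip1, an inhibitor of PI3 kinase, 3.50-fold. The same group held 2 Y-linked genes, Kdm5d (6.37-fold lower) and Eif2s3y (3.60-fold lower), and the neutrophil genes S100a9 (5.30-fold), S100a8 (5.25-fold) and Ltf (3.97-fold). Ager was barely above the dimmest detected probe on the knockout array (log2 5.83 against 5.81).

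**Figure D1:**
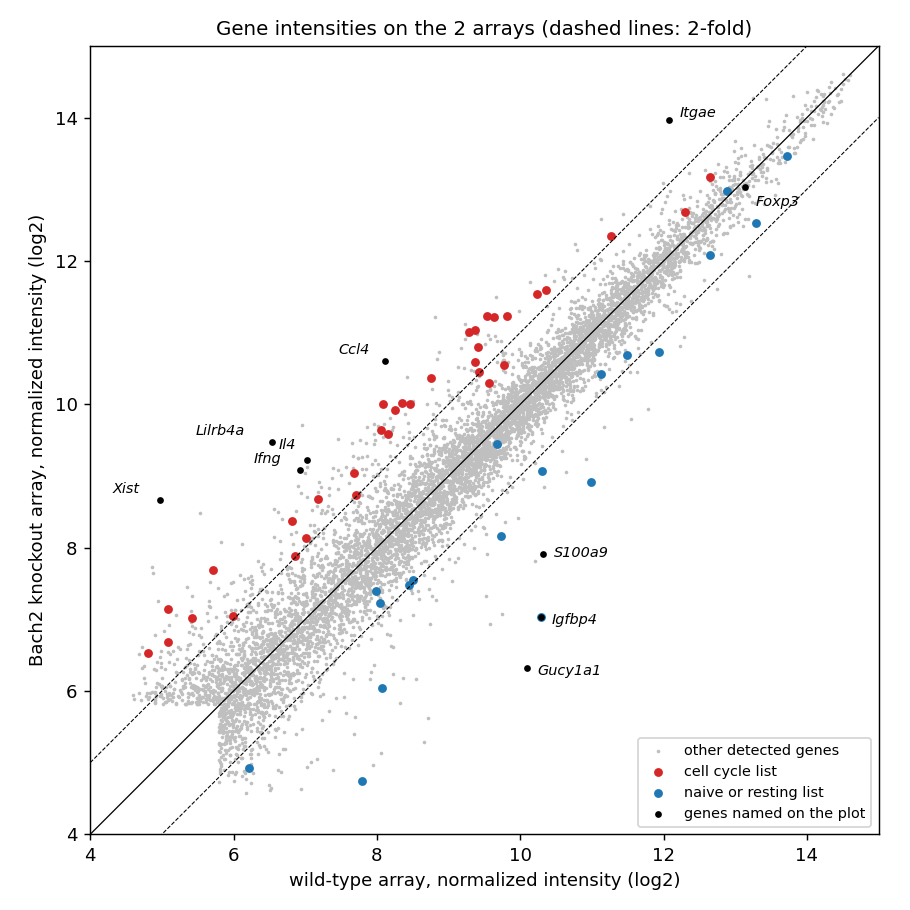
Normalized log2 intensity of each of the 7611 detected genes on the wild-type array (x axis) and the Bach2 knockout array (y axis), with 1 array per genotype; the solid line marks equal intensity and the dashed lines a 2-fold difference. Most cell cycle genes (red) lie above the upper dashed line, all naive or resting genes except Il7r (blue) lie below the solid line, and Foxp3 lies close to it.

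**Figure D2:**
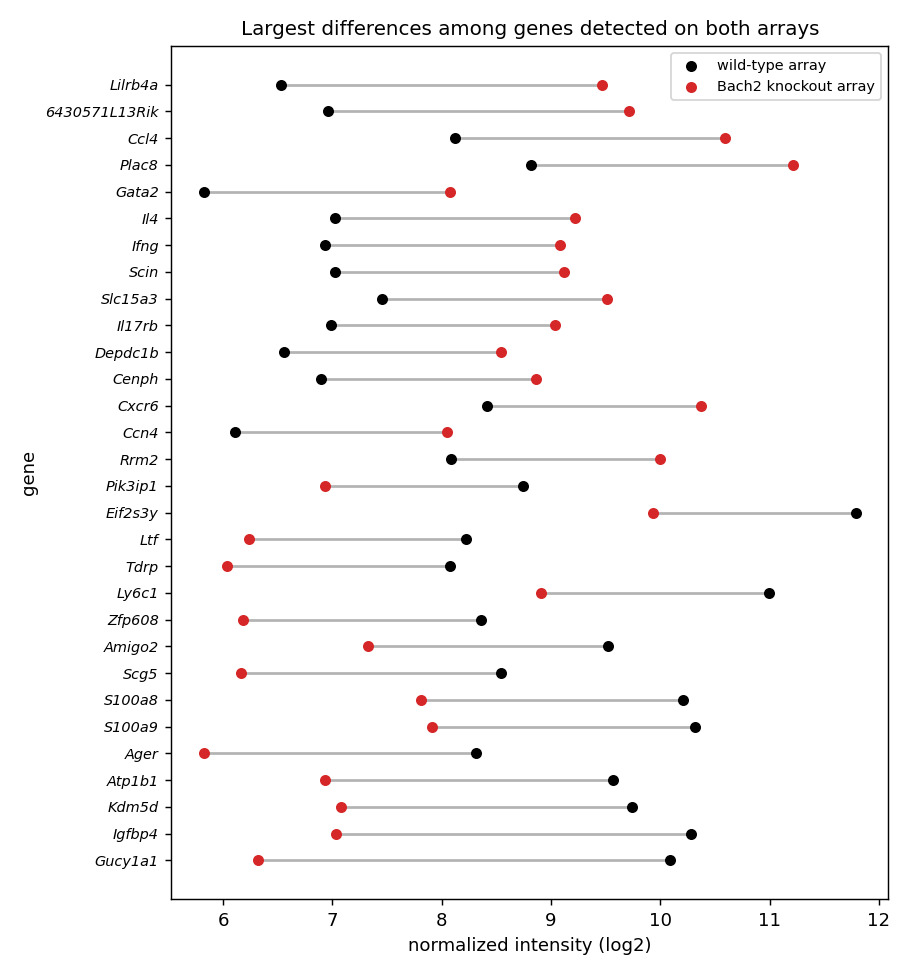
Normalized log2 intensity on the wild-type array (black) and the knockout array (red) of the 15 genes highest and the 15 lowest in the knockout relative to wild type among genes detected on both arrays. The differences run from 2.94 for Lilrb4a to -3.77 for Gucy1a1 on the log2 scale.

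Among genes detected on 1 array only, Dkk3, a secreted Wnt pathway modulator, was at least 6.44-fold higher in the knockout, the chemokine Ccl1 at least 3.81-fold, the cyclin gene Ccne1 at least 3.71-fold and Tmprss3 at least 3.59-fold. Xist, the RNA that silences 1 X chromosome in females, was at least 7.27-fold higher in the knockout and was not detected on the wild-type array. Detected on the wild-type array only were Wfdc2 (at least 7.42-fold lower in the knockout), Cldn10 (at least 7.19-fold), Ampd1 (at least 4.75-fold), Tmem108 (at least 4.37-fold) and Dapl1 (at least 3.95-fold). These bounds set the brighter array against the higher of the gene's own value and the dimmest detected probe on the other array. A dimmer probe therefore gives a smaller bound, and the other detected probes gave at least 1.73-fold and 1.07-fold for Cldn10, 1.92-fold for Ampd1, 5.13-fold for Dkk3 and 3.43-fold for Xist, in the same directions.

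Cell cycle genes were the most uniformly higher group in the knockout. Of 34 detected members, 32 were at least 1.5-fold higher, 28 were at least 2-fold higher and none was lower by 1.5-fold, and the median difference was 1.47 (2.77-fold). The group spanned DNA replication and mitosis. Rrm2 differed by 1.91, Top2a, the topoisomerase of dividing cells, by 1.72, Plk1, a mitotic kinase, by 1.69, Cdk1 by 1.67 and Birc5 (survivin) by 1.67. Ccne1 and Ttk, a spindle checkpoint kinase, were detected in the knockout only, the latter at least 2.53-fold higher. The replication licensing genes Mcm6 and Mcm4 had the smallest differences at the brightest probe, 0.39 and 0.52, although the other Mcm6 probes ranged from 0.36 to 1.09. The list's median lay above those of all 10000 random lists of like intensity, whose central 95% ran from -0.16 to 0.11.

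Genes of naive or resting T cells were lower in the knockout, and genes of effector regulatory T cells were higher. Of 19 detected naive or resting genes, 13 were at least 1.5-fold lower and none was 1.5-fold higher, with a median of -0.96 that lay below those of all random lists. Besides Igfbp4, Dapl1 and Ly6c1, these included Il6st (-1.57), the lymph node homing receptor Ccr7 (-1.24), Id3 (-0.96), Foxp1 (-0.96) and the transcription factor Lef1 (-0.81, second probe -1.51). Il7r, the interleukin 7 receptor, differed by 0.09, and by 0.08 and 0.55 at its other probes. Of 28 detected effector genes, 17 were at least 1.5-fold higher and none was 1.5-fold lower, with a median of 0.75 above that of all random lists. Il10, an inhibitory cytokine, differed by 1.64, Havcr2 (TIM-3) by 1.41, Fgl2, a suppressive effector protein, by 1.31, Id2 by 1.08 and Klrg1, a receptor of terminally differentiated cells, by 0.91. Irf4 differed by 0.63, Gata3 by 0.36 and Batf by 0.27. Prdm1, which encodes Blimp-1, was not detected by the threshold used, with a detection p-value of 0.0113 in the knockout against 0.267 in wild type, so no fold is given. In the overlapping list of tissue regulatory T cell genes, 8 of 15 were at least 1.5-fold higher (median 0.82, and 0.49 on the series matrix values), led by Cxcr6 (1.96) and Itgae, which encodes the epithelial-binding integrin CD103. All 6 Itgae probes were higher in the knockout, by 1.75 to 2.52.

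Genes of the core regulatory T cell list differed in both directions. Of its 21 detected members, 5 were at least 1.5-fold higher, 3 were at least 1.5-fold lower and 13 were within 1.5-fold. Without members shared with other lists, 2 of 14 were higher and 3 were lower (median 0.21, percentile 99.61). Itgae, Il10, Ebi3, a subunit of interleukin 35 (1.33), Socs2 (0.96) and Capg (0.70) were higher, and Gpr83 (-1.13), Ecm1 (-1.08) and Izumo1r, the folate receptor 4 gene (-0.67), were lower. The median of 0.22 was at percentile 99.99 of the random lists.

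Th1 and Th2 genes were both higher in the knockout. Of 12 detected Th1 genes, 8 were at least 1.5-fold higher and none was 1.5-fold lower (median 1.05, above all random lists). They included Ifng (2.15, second probe 1.44), Il18rap (at least 2.18-fold, detected in the knockout only), Il18r1 (1.22), the Th1 master regulator Tbx21 (1.21) and Cxcr3 (1.14), whereas Stat4 differed by -0.19. Of 11 detected Th2 genes, 7 were at least 1.5-fold higher and none was 1.5-fold lower (median 0.97, above all random lists). They included Il4 (2.19), Il17rb (2.05), Ccr8 (1.08), Pparg (at least 1.73-fold) and Il13 (at least 1.52-fold). Ccr8, Pparg, Il10 and Nfil3, all higher, also belong to the effector regulatory T cell list. Without members of more than 1 list, 3 of 5 detected Th2 genes were at least 1.5-fold higher. The transcription factor Stat6 went the other way (-0.58), just short of 1.5-fold, and Il5 was not detected on either array. On the series matrix values 5 of the 11 were at least 1.5-fold higher and the median was 0.49, and with no filter on dim probes 7 of 18 were and the median was 0.35 (percentile 99.98). With an offset of 1, 1 member was 1.5-fold lower. Mast cell and basophil markers were also higher in the knockout: Cpa3 by 1.47, Fcer1a by 1.44, Prss34 by 1.20 and Mcpt8 by 0.96. Only 7 Th17 genes were detected, with a median of 0.27 at percentile 93.0, and Il17a, Il22 and Il23r were not detected. Of 10 detected follicular helper genes, 2 were higher by 1.5-fold (Il21, at least 1.76-fold, and Pou2af1, 0.81) and 2 were lower (Cxcr5, -0.90, and Bcl6, the lineage factor, -0.89). This list's median of 0.42 was at percentile 99.86, but at percentile 88.6 (median 0.12) when only genes detected on both arrays were kept, where 1 of 8 was higher by 1.5-fold.

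Cytotoxic and killer receptor genes were higher as a group. Of 15 detected members, 11 were at least 1.5-fold higher and 1 was 1.5-fold lower (median 0.91, above all random lists). Ccl4, Nkg7 (1.70), Ccl5 (1.57), Ctsw (1.36) and Klrd1 (0.90) were higher, whereas Prf1 (perforin) was lower at its brightest probe (-0.60) and differed by 0.01 at its other probe. Of the granzyme genes, Gzmm differed by -0.27, and Gzma, Gzmb, Gzmc and Gzmk were not detected on either array, so no fold is given for them. Gzmk had a detection p-value of 0.0376 in the knockout against 0.259 in wild type. Markers of NK cells were also higher, with 8 of 11 members at least 1.5-fold higher and a median of 0.73 (percentile 99.97), but 5 of 11 with an offset of 50 and 2 of 11 (median 0.45) on the series matrix values. Of 6 detected CD8 T cell markers, 4 were at least 1.5-fold higher (median 0.91, percentile 99.99), all of them also expressed by other lymphocytes, namely Ccl5, Xcl1 (1.51), Klrk1 (at least 1.64-fold) and Klrd1. On the series matrix values 3 of the 6 were, with a median of 0.51 (percentile 99.93). Cd8a was not detected on either array. Cd8b1 was detected on both arrays, at log2 9.999 in wild type and 10.20 in the knockout. Cd8b1 differed by 0.20, and by 0.15 at its other probe.

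Interferon response genes were modestly lower in the knockout: 6 of 25 detected members were at least 1.5-fold lower, none was 1.5-fold higher, and the median of -0.30 was at percentile 0.03. Rtp4 (-0.95), Usp18 (-0.94), Oasl1 (-0.83) and Mx2 (-0.80) were lowest, and Irf7 differed by 0.06. On the series matrix values, 1 of the 25 was at least 1.5-fold lower and the median was -0.19 (percentile 0.12), and with no filter on dim probes the median was -0.17 (percentile 0.71). Glycolysis genes were slightly higher (median 0.27, percentile 99.82), with 3 of 15 at least 1.5-fold higher, namely Hk2 (1.12), Pgam1 (0.84) and Tpi1 (0.76). The glucose transporters Slc2a1 and Slc2a3 differed by -0.16 and -0.18.

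For 7 of the 18 T cell state and pathway lists the median stayed within the central 95% of the random lists. Of these, the Th17 list is described above. AP-1 and Maf factors had a median of -0.04, with Fos at -0.71, Jdp2 at least 1.82-fold higher (knockout only), Batf at 0.27 and Bach1 at -0.10. Heme and oxidative stress genes, which hold known targets of Bach proteins, had a median of 0.08. Srxn1 differed by 1.08, Osgin1 by -1.01 and Gclm by 0.05, and Hmox1 was not detected on either array. Srxn1 was barely above the dimmest detected probe on the wild-type array (log2 5.83 against 5.80). Genes induced early by the T cell receptor had a median of -0.06, with Ier3 at 0.76, Egr2 at 0.23 and Egr1 at -0.01, and IL-2 and STAT5 response genes 0.13, with Socs2 at 0.96 and Socs3 at -0.93. Apoptosis and survival genes had a median of 0.02. Bcl2 differed by -0.79, and Cdkn2b, a cyclin-dependent kinase inhibitor, was detected in the knockout only, at least 2.88-fold higher. Homing genes had a median of 0.14 at percentile 97.43 and went both ways, with Cxcr6, Itgae, Cxcr3 and Ccr8 higher and Ccr7, Cxcr4 (-0.96) and Cxcr5 lower. Without members of other lists its median was -0.02, and with median scaling it was 0.19 at percentile 98.55, past the limit.

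**Figure D3:**
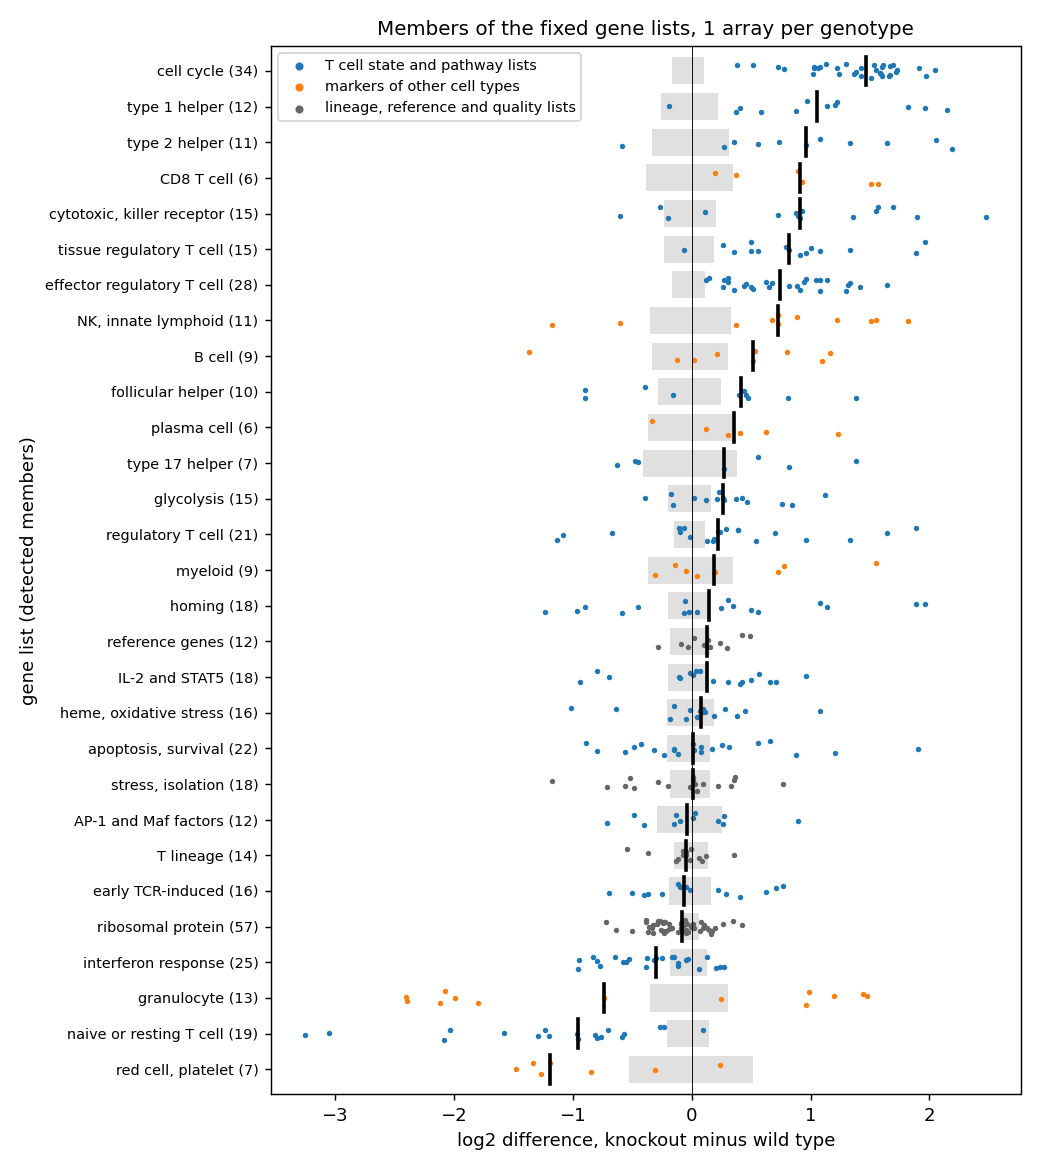
Log2 difference, knockout minus wild type (x axis), of every detected member (points) of the 29 gene lists with at least 5 detected members (y axis, number of members in parentheses). Black bars mark each list's median and grey boxes the central 95% of the medians of 10000 random lists of like intensity. Cell cycle genes have the highest median (1.47) and red cell and platelet genes the lowest (-1.19), and granulocyte genes lie on either side of 0. Members undetected on 1 array are drawn at their value. At their bound, the red cell and platelet median is -0.64, and that of naive or resting genes is lower (-0.81).

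Markers of other cell types differed between the 2 samples. Several neutrophil genes of the granulocyte list were lower in the knockout: S100a8 and S100a9 (above), Camp (at least 2.56-fold lower) and Retnlg (at least 2.41-fold lower). Mmp9, also a neutrophil gene of that list, differed by 0.25. Red cell genes were lower too, with Hba-a1 at -1.34 and Hbb-bt at -1.19. The 7 detected red cell and platelet genes had a median of -1.19, but -0.64 (percentile 0.01) with members undetected on 1 array at their bound, -0.55 on the series matrix values and -0.10 at percentile 20.4 with no filter on dim probes. In the granulocyte list, 7 of 13 detected members were at least 1.5-fold lower and 5 were at least 1.5-fold higher, and the higher ones were the mast cell, basophil and eosinophil genes Cpa3, Fcer1a, Prss34, Prg2 (0.99) and Mcpt8. This list's median of -0.74 turned to 0.61 when only genes detected on both arrays were kept, with 4 of 10 lower and 5 higher. Of the B cell genes, Cd79b (1.16) and Cd22 (1.10) were higher and Fcmr was lower (-1.37), while Ms4a1 and Pax5 were not detected on either array. The median of the 9 detected B cell markers was 0.52 at percentile 99.66, but 0.22 at percentile 91.9 with the mean of each gene's detected probes, 0.18 at percentile 94.9 on the series matrix values and 0.08 at percentile 87.2 with no filter on dim probes. That of the 6 plasma cell markers was 0.36 at percentile 97.99, and 0.30 at percentile 96.3 with genes detected on both arrays. Of 9 detected myeloid markers, 3 were at least 1.5-fold higher and none was 1.5-fold lower (median 0.19, percentile 87.8). The 3 were Tyrobp (at least 2.23-fold, knockout only), Vcam1 (0.77) and Fcer1g (0.73), and Lyz2 differed by 0.04. On the series matrix values 1 of the 9 was at least 1.5-fold higher. Reference genes had a median of 0.13 (percentile 95.3, but 0.21 at percentile 98.97 with the mean of each gene's detected probes), stress and isolation genes 0.01 and ribosomal protein genes -0.08 (percentile 2.28, but 20.3 among random lists not matched on intensity). The Y-linked Uty was detected on the wild-type array only (at least 2.05-fold lower in the knockout). Across the 29 lists, 18 lay outside the central 95% of random lists, against a nominal 1.45. In simulated arrays 6.8% of random lists fell outside, and the lists here share members and are not independent. The simulated noise was independent between genes, whereas genes of 1 list can vary together between any 2 samples. Neither rate is therefore a measure of how many of the 18 would arise without a genotype effect.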

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

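Signal was also present in probes outside the gene comparisons. Of 641 detected probes that the annotation left unnamed, 25 were at least 2-fold higher on the knockout array than on the wild-type array and 8 were at least 2-fold lower. These are 3.90% and 1.25% of them, next to 3.27% and 1.55% of named genes. The largest difference was that of probe ILMN_2819558, which was 14.7-fold lower in the knockout (log2 6.22 against 10.10), and the largest increase was that of ILMN_2648080, 3.71-fold. Groups of 1 array allowed no check for outlying samples and no comparison of effects between groups.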

How the results depend on the processing

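Among the 11 T cell state and pathway lists that stood apart, no median changed sign under the alternatives run. There were 14 alternatives for each gene count and 12 to 15 for each T cell state or pathway list. A gene count has no sign to reverse. Lists that did not stand apart had no call to reverse, and some of their medians took both signs. These ran from -0.11 to 0.01 for AP-1 and Maf factors, -0.11 to 0.06 for apoptosis and survival, and -0.02 to 0.19 for homing genes. Of the 17 different alternatives, 16 were planned and the removal of other cell type and sex-linked genes was chosen after seeing the data. The 249 higher genes numbered 176 with an offset of 50, 132 on the series matrix values, 620 at 1.5-fold and 63 at 3-fold. The 118 lower genes numbered 76 with an offset of 50, 50 on the series matrix values, 515 at 1.5-fold and 31 at 3-fold. The series matrix keeps a constant in every value, which shrinks the fold of dim genes, and no gene was called in the opposite direction under the alternatives that changed the values or the filter. On the series matrix values the list medians were -0.68 for naive or resting, 0.73 for Th1, 0.49 for Th2, 1.09 for cell cycle, 0.49 for tissue regulatory T cell and 0.048 for Th17 genes. With members undetected on 1 array at their bound, they were -0.81 for naive or resting, 0.79 for Th2, 0.09 for Th17 and 0.33 for follicular helper genes. With no filter on dim probes they were 0.35 for Th2 and 0.56 for tissue regulatory T cell genes, and without members of more than 1 list 0.74 for Th2, 1.36 for cytotoxic and 0.12 for follicular helper genes. The follicular helper list no longer stood apart in that setting, nor at 0.12 with genes detected on both arrays or at 0.15 with the mean of detected probes. The homing list crossed the limit at medians of 0.19 (median scaling), 0.18 (cyclic loess) and 0.14 (offset 50, mean of probes, probe with the smallest difference, and members at their bound). The granulocyte list, whose members went both ways, reversed to 0.045 at a detection p-value under 0.05, 0.61 with genes detected on both arrays and 0.13 with no filter. Leaving out other cell type and sex-linked genes gave 239 higher and 106 lower genes. For the 40 genes named by size, 331 of 430 alternative values stayed within 1 SD between probes, 99 moved by more, 77 of them towards 0, and none reversed. No value for Bach2 was computed under any setting, because no probe was paired with it in the annotation used here. No paired analysis was possible because each genotype has 1 array. Signal over background is a further limit, since 40.6% of probes on the wild-type array and 40.4% on the knockout array were above background by the threshold used.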

Other observations

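Further gene families, 10 in all, were examined after the values had been seen, and the tests below were chosen after the result was seen except the test of further basophil genes. Histone genes were higher in the knockout: 27 of 45 detected members were at least 1.5-fold higher and 1 was 1.5-fold lower, with a median of 0.79, and H2ac15 (1.62) and H2ac7 (1.41) were highest. The member past 1.5-fold lower was H2bc4 (-0.64), and others were lower by less, including H2aj (-0.55) and H2bc18 (-0.48). Histone genes are near-identical in sequence, and cross-hybridisation between their probes was not tested. Of 16 centromere and kinetochore genes, 11 were at least 1.5-fold higher, including Cenph (1.96), Spc25 (1.80) and Cenpp (1.72). Of 10 chemokine ligand genes, 7 were higher by at least 1.5-fold. These included Ccl9 (1.87), Xcl1 (1.51) and Cxcl10 (at least 2.45-fold, knockout only), while Ccl27a (-0.58) and Ccl25 (-0.53) were lower. Of 8 Kruppel-like factor genes, none was 1.5-fold higher and 3 were 1.5-fold lower, Klf7 (-1.48), Klf13 (-0.77) and Klf3 (-0.67), with a median of -0.62 below those of all random lists. Across the alternatives that changed the values, the filter or the probe choice, the median of each of these families kept its direction, from 0.48 to 0.83 for histones, 0.63 to 1.14 for centromere and kinetochore genes, 0.14 to 1.70 for chemokine ligands and -0.62 to -0.26 for Kruppel-like factors. Metallothionein Mt1 was higher by 1.90. Of 16 kinesin genes, 8 were at least 1.5-fold higher and 1 was at least 1.5-fold lower (median 0.69, and 0.13 with no filter on dim probes). Of 8 killer cell lectin-like receptor genes, all of which the fixed lists hold, 7 were at least 1.5-fold higher (median 0.89, and 0.06 with no filter). The remaining families held few or no genes past 1.5-fold. Of 35 genes picked by the symbols of proteasome subunits, 1 was higher by that much, Psmc3ip (0.85) (family median 0.17, percentile 99.97). Psmc3ip is named for its binding to a subunit and does not encode a proteasome subunit, and the next highest was Psmb9 (0.47). Of 77 oxidative phosphorylation genes, 2 were higher and 1 was lower (median 0.11, percentile 99.99). None of 8 GIMAP genes passed (median -0.28, percentile 0.58). The medians of these families were small but outside the central 95% of random lists.

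Both donors were labelled male, but the knockout array carried Xist (intensity 393 and 178 at its 2 probes, against 12.3 and -1.07 in wild type), and Y-linked genes were lower there. Kdm5d was at 14.1% and Eif2s3y at 27.4% of their background-corrected wild-type intensity. A candidate explanation is RNA of male and female mice mixed in the knockout sample. The 2 shares differ by 0.96 on the log2 scale, more than the scatter between probes, so a single mixing proportion is not settled. A wholly female sample also stays open, because the 2 Y-linked probes detected on the knockout array belong to genes with X-linked homologues whose RNA might bind them, and an effect of genotype on these genes was not tested.

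Cell cycle genes were higher and naive or resting genes lower while Foxp3 was at a like level. The processing alone is argued against, since the smaller of the 2 list medians stayed at 0.68 or more in size under every alternative run. Replacement of regulatory T cells by activated cells lacking Foxp3 would lower Foxp3 about as much as the naive list (median -0.96). The lowest of 3 Foxp3 probes was at -0.37. With this median, that argues against replacement as the whole source of the lower naive genes, if Foxp3 per cell was unaltered. The gap asked for was more than 2 SD between probes (SD 0.22). It was narrowly missed with undetected naive members at their bound (median -0.81), so the argument depends on this choice. A smaller admixture could still add to Ifng or the cell cycle genes. An effect of the genotype was not tested apart from the age gap, the sex-linked difference and animal-to-animal variation, and all of these stay open.

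Mast cell and basophil genes were higher in the knockout together with Il4 and Gata2, although the sort selected CD4-positive cells. Of the further basophil and mast cell genes listed before their values were seen, only 4 were detected, and 3 of these (75.0%) were at least 1.5-fold higher, against 8.15% of all genes: Lat2 (1.41), Aqp9 (1.24) and Cyp4f18 (0.95). This is consistent with more such cells, or their RNA, in the knockout sample, though Lat2 is also used by B cells and myeloid cells. Whether Il4 came from them is open: its background-corrected intensity was 5.07 times the wild-type value, within the range of 2.21 (Mcpt8) to 6.23 (Gata2) of basophil genes detected on both arrays, but only because of Gata2, since the next highest ratio was 3.21 (Cpa3). Gata2 was barely above the dimmest detected probe on the wild-type array (log2 5.83 against 5.80), so its ratio rests on a value near background. The markers were dim, with Mcpt8 at an intensity of 131 and Prss34 at 309 in the knockout, and Ms4a2 was not detected (detection p-value 0.0451 in the knockout).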
